A study of Mus musculus with 4 samples.

How the data were processed

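RNA-seq was done on plasmacytoid dendritic cells (pDCs) grown from C57BL/6 mouse bone marrow precursors for 8 days in Flt3 ligand and stimulated for 24 h with imiquimod at 1 µg/ml, per the labels' protocols. The sort used SiglecH and CD11b, and the cells were divided by the BFP that reports Cxcl10; the sources used here do not make clear whether the CD11b gate was low or high, nor where the BFP gate lay. The titles give the libraries of each replicate number a shared code whose meaning is not given in the sources used here. Per the labels' protocols, RNA was purified with a Qiagen RNeasy kit and cDNA libraries were made with the SMART-Seq kit from Clontech, which amplifies full-length cDNA by PCR and does not mark strand or single molecules. The 4 libraries fall into BFP-positive and BFP-negative cells, with 2 in each group, by the sample titles. A population label of the BFP-negative samples calls them positive for CXCL10 and negative for BFP, whereas the design text of the series calls that population negative for both, so only the BFP part of the label was used.

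The authors deposited a table of raw counts per gene for all libraries and, for each library, a table of log2 RPKM values (on the log2 scale, reads scaled to gene length and library total). The submitters' processing notes name Subread, featureCounts and limma with the builds GRCm38 and mm10; no versions, and neither the treatment of reads that match several places nor a strand setting, are given in the sources used here. The deposited counts are whole numbers without normalization, while the deposited log2 RPKM values are corrected by the authors for gene length and library total. The count table held 27179 genes with an Entrez identifier, of which 855 had no symbol and 25275 matched the RefSeq annotation of GRCm38, the source of the printed positions. Reads of near-identical copies may be split or lost, so values of the Ifitm, Ms4a and Oas1 families, Tgtp1 and Tgtp2, Bcl2a1 genes, immunoglobulin segments, histone genes, class I genes of the H2-Q group, ribosomal protein genes, Gapdh (12.7 ± 3.32 CPM in BFP-negative cells) and Pgk1 (9.28 ± 0.967 CPM) are uncertain. Genes that overlap on opposite strands cannot be told apart where they overlap, because the libraries do not mark strand. The interferon genes are also a family of near-identical copies, so their low counts are uncertain too.

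Library totals were 11868254 to 12570117 counts, so 1 count was worth 0.0796 to 0.0843 CPM and the 3 counts that a count of 0 allows were worth 0.239 to 0.253 CPM. Such floors, and the counting interval given for Csf1r, which is an exact binomial interval at 95%, cover counting error only, because PCR copies are not independent molecules. The 10 most abundant genes took 8.44% to 9.99% of the counts, Rn45s 0.901% to 1.12%, the mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 together 0.260% to 0.427% and ribosomal protein genes 2.38% to 3.11%. Replicates were separate libraries by their counts, with a chi-square per degree of freedom of 19.8 in BFP-negative and 15.5 in BFP-positive cells. Their log2 CPM values correlated at 0.955 and 0.960 across genes within the groups and at 0.910 to 0.916 between them, where genes are not independent replicates.

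Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), which left 11706 genes and at least 99.9% of the counts of each library; 15473 genes were not tested. TMM factors were 0.973 to 1.04. The comparison was BFP-positive against BFP-negative in edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with the group as the only term, 2 residual degrees of freedom, a biological coefficient of variation of 24.7%, two-sided p-values and Benjamini-Hochberg adjustment over all genes tested, at an adjusted p threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are TMM-scaled CPM. Of the fixed gene lists, 29 in number with 562 entries, 548 entries matched a gene of the count table and 14 did not, 13 of them mitochondrial messenger RNAs. The 26 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset inter-gene correlation 0.01), two-sided, with Benjamini-Hochberg adjustment over the lists. Camera asks whether the genes of a list rank higher or lower than all other genes; fry asks whether the genes of a list move, on balance, in one direction and does not compare them with other genes.

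The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Cxcl10, Cxcl9, Siglech, Itgam, Bst2 and Tlr7 in any case. It adds the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold with a mean of at least 20 CPM and both groups apart, leaving out predicted genes, and the 2 members with the smallest p of each list. Some of these genes are not reported here. Other list members named as examples were chosen after their values were seen. Genes named by this rule numbered 77, of which 76 were tested and 62 passed.

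The lists were type I and III interferons, interferon-stimulated genes, interferon-gamma-type GTPases, chemokines other than Cxcl10, inflammatory cytokines, NF-kB targets and regulators, pDC identity, pDC subset markers, conventional dendritic cells, dendritic cell maturation and costimulation, MHC class II and class I presentation, endosomal TLR signalling, unfolded protein response and secretion, cell cycle, apoptosis and survival, glycolysis, oxidative phosphorylation, cholesterol synthesis, chemokine receptors and homing, ribosomal proteins, immediate early and stress genes, mitochondrial transcripts, monocytes and macrophages, granulocytes and mast cells, B cells, T, NK and innate lymphoid cells, erythroid cells and progenitors, and sex-linked genes. Interferons, mitochondrial transcripts and sex-linked genes had 1, 2 and 4 tested members and were not tested as sets.

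Alternatives were median-of-ratios size factors, library totals alone and upper-quartile factors in place of TMM; no filter, and a stricter filter of at least 50 counts in sum and 1 CPM on average; DESeq2 1.42.0; limma-voom; limma on the deposited log2 RPKM values; robust dispersion; a test against a fold of 1.5; the replicate number as a block; leaving out each library; and, for the lists, camera with an estimated correlation, fry, and camera with a prior count of 0.5. The gene tests of edgeR, DESeq2 and limma-voom were tried on simulated data, 5 data sets of 11706 genes with 200 changed in each. Means, dispersions and library sizes were those of this comparison. Both forms of camera and fry were tried on further data sets drawn in the same way. The other alternatives and the tests of the closing section were not tried on simulated data. The simulated genes were drawn independently of one another. At folds of 1.5, 2, 3 and 4, edgeR's test recovered 14%, 46%, 69.2% and 70.8% of the changed genes, with 5.84% of its calls false. For DESeq2 the shares recovered were 19.2%, 49.2%, 71.6% and 73.6%, with 8.25% of calls false, and for limma-voom 14.8%, 44%, 66.4% and 68.8%, with 4.72% false. In the closing section, gene length and GC content come from the longest annotated transcript of each gene in GENCODE vM21.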

Results

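Plasmacytoid dendritic cells (pDCs) are immune cells that sense viral nucleic acids through endosomal Toll-like receptors and are known for secreting type I interferon. Here they were grown from C57BL/6 mouse bone marrow precursors for 8 days with Flt3 ligand, a growth factor that drives dendritic cell development, and were stimulated for 24 h with imiquimod at 1 µg/ml, a small-molecule ligand of TLR7. The pDCs were then sorted with SiglecH and CD11b and split by a blue fluorescent protein (BFP) that reports the chemokine gene Cxcl10. The labels do not make clear whether cells low or high in CD11b were taken, nor where the BFP gate lay. RNA-seq was done on 4 libraries, 2 from BFP-positive and 2 from BFP-negative cells of the stimulated cultures. The count table held 12018387 and 12570117 counts for BFP-negative replicates 1 and 2, and 11868254 and 12497526 for BFP-positive replicates 1 and 2. Between 13219 and 13533 genes had at least 1 count in a library. No unstimulated library was analysed here. The single comparison asks how pDCs that switched on the Cxcl10 reporter differ in their transcripts from stimulated pDCs that did not. Levels are CPM (counts scaled to a common library total), given as mean ± SD with n = 2 libraries per group, and log2 fold changes are BFP-positive over BFP-negative with their standard error (SE). Gene positions are whole genes, introns included, on the mouse assembly GRCm38.

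Cxcl10 itself (Entrez gene 15945, chromosome 5, 92346638 to 92348889) was 14.4-fold higher in the BFP-positive cells, at 12.7 ± 0.0787 CPM against 0.870 ± 0.889 CPM. Its log2 fold change was 3.85, SE 0.68, with an adjusted p of 0.00557 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Because the sort used a reporter of this gene, its rise checks the labels and is no finding. The BFP-negative libraries held 3 and 19 Cxcl10 counts and the BFP-positive libraries 149 and 154. The size of the rise rested on the BFP-negative pair, with a log2 fold change of 3.08 without BFP-negative replicate 1 and 5.68 without BFP-negative replicate 2. Cxcl9, a related chemokine gene, had no count in the BFP-negative libraries and 6 and 1 counts in the BFP-positive ones, too few to be tested. Among the genes of the sort, Siglech (Entrez gene 233274, chromosome 7, 55768154 to 55779448) was at 613 ± 2.69 CPM in BFP-negative and 803 ± 25.04 CPM in BFP-positive cells (log2 fold change 0.39, SE 0.11, adjusted p = 0.0485). That call was lost when any 1 of the 4 libraries was left out, with adjusted p = 0.0922, 0.0716, 0.177 and 0.287 without BFP-negative replicates 1 and 2 and BFP-positive replicates 1 and 2. Itgam, which encodes CD11b, was at 2.93 ± 1.65 and 10.1 ± 0.712 CPM and did not pass the test (log2 fold change 1.78, SE 0.52, adjusted p = 0.0546). It did pass without BFP-negative replicate 2 (2.53, adjusted p = 0.00924), and also with no filter on low counts, DESeq2 and limma-voom (adjusted p = 0.0387, 0.0387 and 0.0419), so the CD11b gene lies close to the threshold. Bst2, which encodes a pDC surface antigen, was at 1717 ± 212 and 1706 ± 48.6 CPM (log2 fold change -0.01, SE 0.12). Tlr7, the receptor of imiquimod, was at 89.2 ± 15.3 and 60.6 ± 1.19 CPM (log2 fold change -0.56, SE 0.18, adjusted p = 0.0781). Without BFP-negative replicate 2 the log2 fold change of Tlr7 was -0.70. With the replicate number as a block, Tlr7 passed in edgeR and limma-voom (adjusted p = 0.0360 and 0.0278) but not in DESeq2.

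Of 11706 genes tested, 890 were higher and 411 lower in BFP-positive cells, and 591 and 158 of these differed at least 2-fold. Among the genes that rose most were Cyp7b1, an oxysterol hydroxylase, at 1.11 ± 0.436 against 54.7 ± 9.67 CPM, and Anxa2, which encodes a calcium-dependent membrane-binding protein, at 5.54 ± 1.14 against 200.3 ± 30.2 CPM. Their log2 fold changes were 5.61, SE 0.35 and 5.17, SE 0.22. Ms4a6b rose 27.2-fold, from 9.66 ± 1.39 to 263 ± 5.38 CPM. The gene of the calcium-binding protein S100a4 rose 21.5-fold, from 27.8 ± 4.14 to 598 ± 157 CPM. Il1b, which encodes the inflammatory cytokine interleukin-1β, went from 11.8 ± 3.33 to 276 ± 15.4 CPM (log2 fold change 4.54, SE 0.21, adjusted p = 2.01e-06). Tbc1d4, a regulator of vesicle traffic, and Cacnb3, a calcium channel subunit seen in mature dendritic cells, rose by log2 5.04, SE 0.32 and 5.03, SE 0.35. Tnfsf9, a costimulatory ligand of the TNF family, rose from 2.15 ± 0.591 to 64.3 ± 7.25 CPM. Ifitm1, an interferon-inducible membrane protein, had 12.1 ± 10.4 and 448 ± 181 CPM. Its log2 fold change of 5.21, SE 0.51 ran from 4.53 without BFP-negative replicate 1 to 6.58 without BFP-negative replicate 2, and with robust dispersion the call was lost (adjusted p = 0.0581). Fscn1, an actin-bundling protein of mature dendritic cells, had 6.27 ± 3.29 and 139.8 ± 12.8 CPM. Its log2 fold change of 4.47, SE 0.31 was 5.17 without BFP-negative replicate 2.

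Falls were smaller. Iglc1, an immunoglobulin lambda constant segment, went from 71.1 ± 14.6 to 11.3 ± 6.04 CPM (log2 fold change -2.66, SE 0.34; -3.34 without BFP-positive replicate 1 and -2.19 without BFP-positive replicate 2). Lta, which encodes lymphotoxin alpha, fell 4.65-fold, from 136 ± 1.86 to 29.1 ± 2.47 CPM (log2 fold change -2.22, SE 0.17, adjusted p = 3.41e-05). The chemokine gene Ccl3 was abundant and fell 3.25-fold, from 2485 ± 278 to 764 ± 44.4 CPM. Xcl1 fell 3.29-fold, from 105 ± 0.773 to 31.9 ± 1.43 CPM. Mzb1, an endoplasmic reticulum chaperone of antibody-secreting cells and pDCs, fell from 59.0 ± 20.2 to 13.8 ± 2.78 CPM. Tnfsf15, a TNF-family ligand, fell from 55.5 ± 10.4 to 13.2 ± 0.858 CPM. The lipase gene Mgll, the immunoglobulin segments Iglc2 and Iglv1, and Ppfia3 followed, with log2 fold changes of -1.89, -1.73, -1.68 and -1.65 and SE of 0.27, 0.25, 0.23 and 0.28, in that order. All 4 libraries separated by group on the first principal component, which held 61.1% of the variance. The values of the 2 groups did not overlap in 54.23% of the tested genes, where chance gives 33.33%. The counts of calls depended on single libraries, with 559 genes higher without BFP-positive replicate 2 and 245 lower without BFP-positive replicate 1. By library totals alone the split was 813 higher and 574 lower.

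The genes named most often map as follows on GRCm38. Cyp7b1 (Entrez gene 13123) lies on chromosome 3 from 18071944 to 18243890. Ifitm1 (Entrez gene 68713) is on chromosome 7 at 140967429 to 140969827. Anxa2 (Entrez gene 12306) lies on chromosome 9 from 69453683 to 69491792. Tbc1d4 (Entrez gene 210789) is on chromosome 14 at 101442360 to 101609281. Cacnb3 (Entrez gene 12297) lies on chromosome 15 from 98628436 to 98644536. Tnfsf9 (Entrez gene 21950) is on chromosome 17 at 57105287 to 57107758. Ms4a6b (Entrez gene 69774) lies on chromosome 19 from 11518559 to 11530403. Il1b (Entrez gene 16176) is on chromosome 2 at 129364569 to 129371164. Fscn1 (Entrez gene 14086) lies on chromosome 5 from 142960355 to 142973189. S100a4 (Entrez gene 20198) is on chromosome 3 at 90603770 to 90606045. Iglc1 (Entrez gene 110785) lies on chromosome 16 from 19061752 to 19062071. Lta (Entrez gene 16992) is on chromosome 17 at 35203165 to 35205578. Mzb1 (Entrez gene 69816) lies on chromosome 18 from 35647265 to 35650266. Tnfsf15 (Entrez gene 326623) is on chromosome 4 at 63724600 to 63745059. Mgll (Entrez gene 23945) lies on chromosome 6 from 88724412 to 88828360. Iglc2 (Entrez gene 110786) is on chromosome 16 at 19198536 to 19198852. Xcl1 (Entrez gene 16963) lies on chromosome 1 from 164931644 to 164935522. Ccl3 (Entrez gene 20302) is on chromosome 11 at 83647843 to 83649378. Iglv1 (Entrez gene 16142) lies on chromosome 16 from 19085017 to 19085460. Ppfia3 (Entrez gene 76787) is on chromosome 7 at 45339126 to 45367019. Rtp4 (Entrez gene 67775) lies on chromosome 16 from 23520219 to 23614222. Gbp2 (Entrez gene 14469) is on chromosome 3 at 142620663 to 142638008. Lgmn (Entrez gene 19141) lies on chromosome 12 from 102394082 to 102439728. Cd14 (Entrez gene 12475) is on chromosome 18 at 36725064 to 36726815. Csf1r (Entrez gene 12978) lies on chromosome 18 from 61105572 to 61131139. Ccr9 (Entrez gene 12769) is on chromosome 9 at 123767211 to 123783457. Pdia4 (Entrez gene 12304) lies on chromosome 6 from 47796141 to 47813512. Ube2c (Entrez gene 68612) lies on chromosome 2 from 164769929 to 164772902. Gpr183 (Entrez gene 321019) is on chromosome 14 at 121952331 to 121965193.

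**Figure D1:**
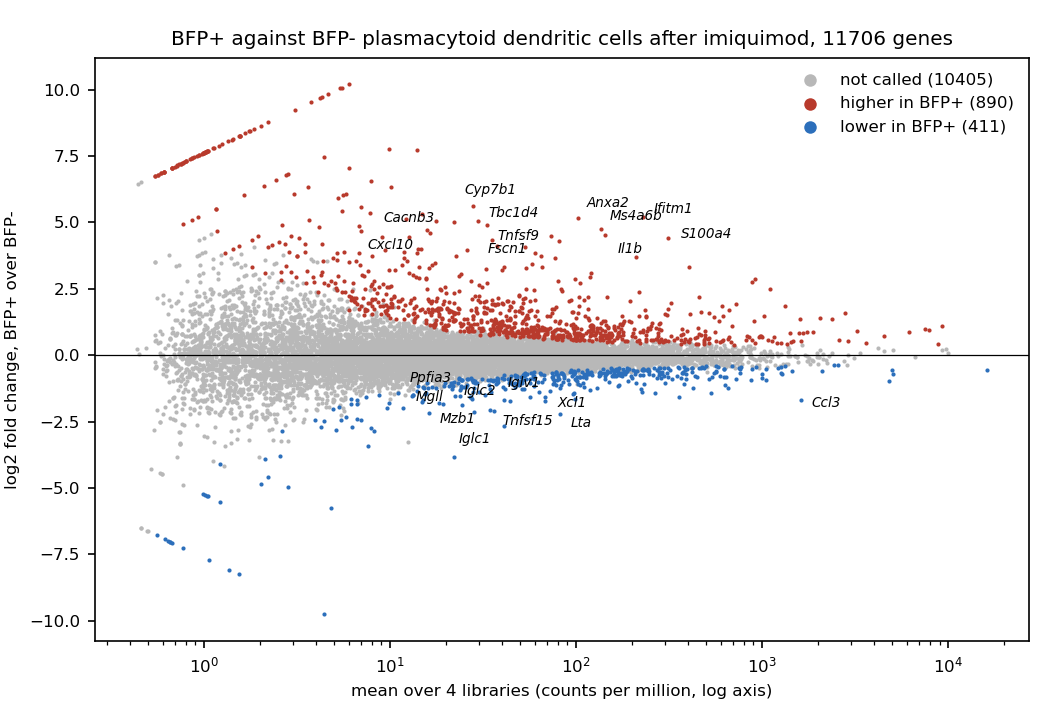
Log2 fold change of BFP-positive over BFP-negative pDCs (vertical axis) against the mean level over the 4 libraries in CPM (horizontal log axis), 1 point per gene for the 11706 genes tested, with the 890 genes that were higher in red, the 411 that were lower in blue and the rest in grey. Labelled are Cxcl10 and the genes with the largest rises and falls among those of at least 20 CPM whose groups did not overlap; the straight lines of points at either edge are genes with no count in a group, whose fitted fold change is no measured size.

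Interferon-stimulated genes, the core antiviral response to type I interferon, were higher as a group in BFP-positive cells. Of 36 members, 19 rose and 2 fell (23 and 2 adjusted over the list alone). The median log2 fold change was 0.65, with camera's adjusted p = 1.29e-07, against adjusted p = 0.311 with an estimated correlation. Rtp4 rose from 23.8 ± 0.754 to 173 ± 2.08 CPM and Oas1a from 11.9 ± 1.81 to 119 ± 23.1 CPM. Isg20 rose from 26.4 ± 3.99 to 141 ± 14.2 CPM. Irf7, the main transcription factor of interferon alpha genes, rose 1.59-fold from 773 ± 140.0 to 1229 ± 16.6 CPM. Oasl1, which is known to restrain Irf7 translation, fell 2.09-fold from 408 ± 26.1 to 195 ± 46.6 CPM. The other member that fell, Ifi44, lost its call without BFP-negative replicate 1 or BFP-positive replicate 1 (adjusted p = 0.170 and 0.212). Isg15 was at 619 ± 29.0 and 692 ± 29.8 CPM (log2 fold change 0.16, SE 0.11) and did not pass the test. The list of interferon-gamma-type GTPases held guanylate-binding proteins and immunity-related GTPases, and also Irf1, Socs1 and Ido1, which are not GTPases. These genes are typical of the response to interferon gamma. Of 17 members, 8 rose, Irf1 and Socs1 among them (9 rose adjusted over the list alone). Their median log2 fold change was 0.91, with camera's adjusted p = 0.00713, against adjusted p = 0.311 with an estimated correlation. Gbp2 rose 11.1-fold, Gbp3 13.3-fold and Irf1 1.88-fold. Without BFP-positive replicate 1 the number of members that rose was 3. Of 19 interferon genes, 18 were too low to be tested and 14 had no count in any library. Each of these 14 was then not detectable above the 3 counts that a count of 0 allows, 0.239 to 0.253 CPM in a library. That bound covers counting error only. Reads of near-identical interferon copies may have been lost, so it does not bound the level of their RNA. Ifnl2, an interferon lambda gene, was at 3.97 ± 1.19 and 2.82 ± 0.0237 CPM (log2 fold change -0.50, SE 0.62).

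Genes of MHC class II antigen presentation were higher in BFP-positive cells. Of 13 members, 10 rose (12 adjusted over the list alone). As a group their median log2 fold change was 0.95, with camera's adjusted p = 6.67e-06, against adjusted p = 0.591 with an estimated correlation. Cd74, the invariant chain and among the most abundant transcripts, went from 5927 ± 1275 to 12737 ± 97.2 CPM. H2-Eb1 rose from 1333 ± 86.7 to 3428 ± 92.04 CPM and the protease gene Ctss from 891 ± 18.4 to 2291 ± 82.5 CPM. The lysosomal genes Lgmn and Ifi30 rose 6.52-fold and 4.22-fold. Ciita, the transactivator of the class II genes, was at 122 ± 15.7 and 96.9 ± 21.7 CPM and did not pass the test. Dendritic cell maturation and costimulation genes rose in 11 of 19 cases and fell in 1 (11 and 2 adjusted over the list alone). Over the list the median log2 fold change was 1.97, with camera's adjusted p = 9.33e-06, against adjusted p = 0.311 with an estimated correlation. Cd83 rose 6.87-fold to 140.1 ± 34.8 CPM and Marcks 3.92-fold to 64.1 ± 1.91 CPM. Cd200 rose 3.26-fold to 54.0 ± 12.3 CPM and the costimulatory receptor gene Cd40 1.86-fold to 159.9 ± 5.20 CPM. The member that fell was Ccr7, the lymph node homing receptor, at 2759 ± 93.6 and 2131 ± 175 CPM (log2 fold change -0.37, SE 0.11, adjusted p = 0.0487). Its call was lost without BFP-negative replicate 2, BFP-positive replicate 1 or BFP-positive replicate 2, where adjusted p = 0.116, 0.371 and 0.115. Cd86 was at 54.6 ± 0.346 and 69.7 ± 2.93 CPM and did not pass.

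Markers of conventional dendritic cells, which the same cultures also produce, rose in 5 of 17 cases and fell in 1 (9 and 1 adjusted over the list alone). The median log2 fold change was 0.83, with camera's adjusted p = 0.000932, against adjusted p = 0.554 with an estimated correlation. Without BFP-negative replicate 2, 9 members rose. The member that fell was Cadm1, whose call was lost without BFP-negative replicate 2, BFP-positive replicate 1 or BFP-positive replicate 2 (adjusted p = 0.0838, 0.0562 and 0.106). With all libraries, the 5 members that rose were Clec4n, Naaa, Clec4a2, the transcription factor gene Zbtb46 and Itgax. Naaa rose 2.02-fold from 99.1 ± 6.51 to 200.1 ± 38.1 CPM. Clec4n was at 0.276 ± 0.390 and 13.6 ± 3.88 CPM, with a log2 fold change of 5.57, SE 0.84 that was 4.61 without BFP-negative replicate 1 and 10.37 without BFP-negative replicate 2. The last is a fit to 0 counts in the remaining BFP-negative library and no measured size. Id2, a transcription factor of conventional dendritic cells, was at 453 ± 48.5 and 486 ± 32.4 CPM and did not pass. Of the monocyte and macrophage markers, 4 of 11 rose and 2 fell (4 and 2 adjusted over the list alone), and the list as a whole was not called (camera's adjusted p = 0.451). These moved beside the rise of the class II, maturation, conventional dendritic cell and interferon-stimulated genes. Cd14 rose from 10.1 ± 0.373 to 97.6 ± 2.47 CPM. Csf1r rose from 3 counts over the BFP-negative libraries to 663 over the BFP-positive ones. That is a ratio of 233, with an exact 95% counting interval of 79.5 to 1134. The fitted log2 fold change of Csf1r was 7.74; it was 6.81 without BFP-negative replicate 2 and 11.40 without BFP-negative replicate 1, the last again fitted to 0 counts and no measured size. Apoe, abundant in macrophages, fell from 13.9 ± 4.49 to 1.31 ± 0.217 CPM. Adgre1, which encodes the macrophage marker F4/80, fell from 30.2 ± 7.54 to 8.45 ± 2.48 CPM. Cd68 was at 263 ± 19.99 and 282 ± 13.7 CPM and did not pass.

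**Figure D2:**
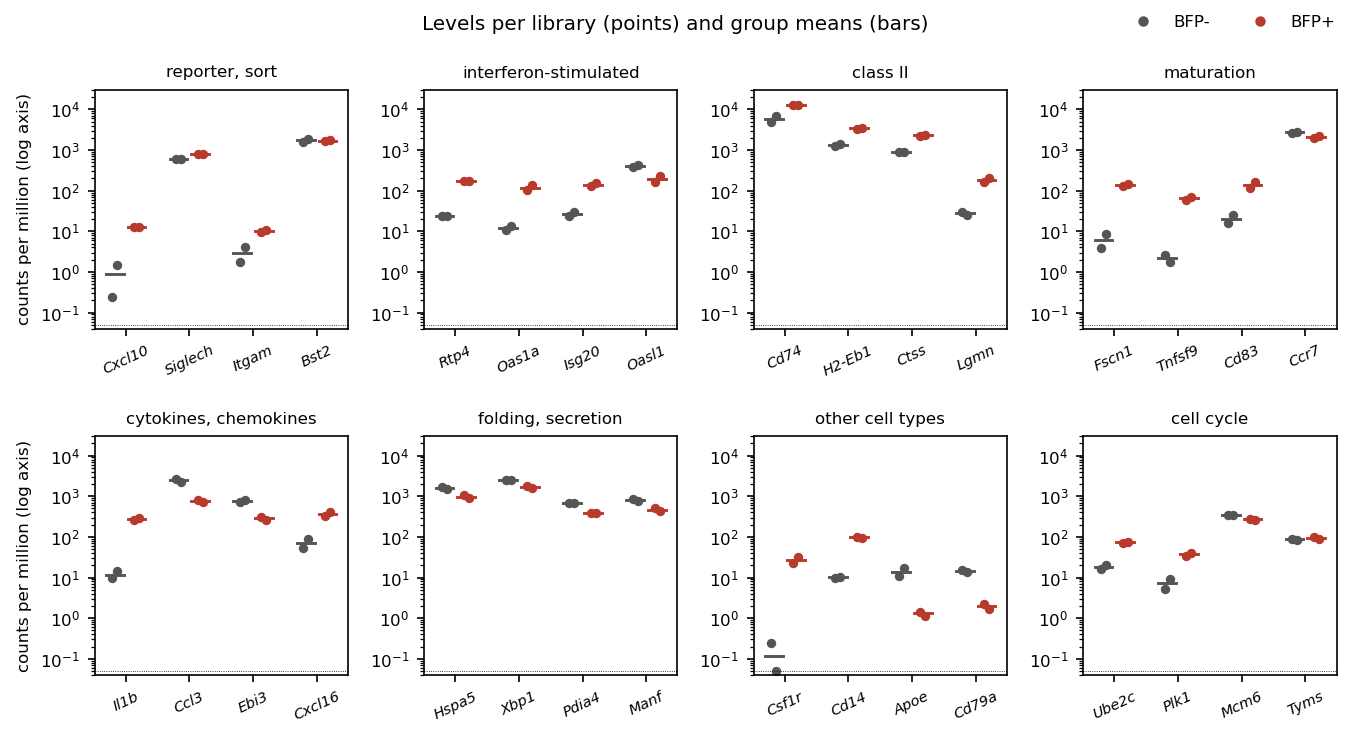
Levels in CPM (vertical log axis) of 4 genes in each of 8 groups, 1 point per library, grey for BFP-negative and red for BFP-positive, with bars at the group means; the dotted line near the lower edge marks where a value of 0 is drawn. Cd74, Ctss, Il1b and Ube2c lay higher in both BFP-positive libraries than in both BFP-negative ones, and Ccl3, Ebi3, Hspa5 and Pdia4 lower.

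Chemokines and inflammatory cytokines moved in both directions. Of 9 tested chemokine genes other than Cxcl10, 3 rose and 3 fell (4 and 4 adjusted over the list alone). Cxcl16 rose 5.25-fold to 365 ± 51.7 CPM and Ccl5 2.70-fold to 349 ± 49.6 CPM, against the falls of Ccl3 and Xcl1. The list was not called (camera's adjusted p = 0.860), and its mean of 0.48 and median of -0.58 differed in sign, with camera's direction downward. Of 13 cytokine genes, 2 rose and 4 fell (3 and 4 adjusted over the list alone), with camera's adjusted p = 0.848. Beside the rise of Il1b, Ebi3, a subunit of heterodimeric cytokines, fell 2.66-fold from 772 ± 64.6 to 290.3 ± 32.7 CPM. Tnf fell 2.11-fold from 139 ± 27.5 to 66.2 ± 9.34 CPM. Il12b was at 79.4 ± 5.87 and 84.2 ± 4.86 CPM and did not pass. Among NF-kB targets and regulators, 6 of 20 rose and 3 fell (8 and 3 adjusted over the list alone), with camera's adjusted p = 0.0515. Without BFP-negative replicate 1 the number that rose was 3 and without BFP-positive replicate 2 it was 1. Without BFP-negative replicate 2 the list passed at adjusted p = 0.0332. Nfkbiz fell 1.68-fold and Cflar 1.72-fold. Tnfaip2 was at 0.799 ± 0.461 and 17.4 ± 5.13 CPM, a log2 fold change of 4.43, SE 0.53 that was 5.18 without BFP-negative replicate 1. Chemokine receptors and homing molecules rose in 6 of 15 cases and fell in 2 (7 and 3 adjusted over the list alone), with camera's adjusted p = 0.113. The list passed without BFP-negative replicate 2 at adjusted p = 0.0461. Gpr183, a receptor of hydroxylated oxysterols, rose 8.47-fold from 25.4 ± 3.10 to 215 ± 12.8 CPM and Ccr2 3.05-fold from 50.8 ± 7.43 to 155 ± 24.5 CPM. The integrin gene Itgal fell 2.16-fold. The other member that fell, Ccr7, kept its call only without BFP-negative replicate 1.

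The pDC identity genes did not move together. Of 25 members, 4 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of -0.11 and camera's adjusted p = 0.953. The number that rose was 2 without either BFP-positive replicate 1 or BFP-positive replicate 2, and the number that fell was 3 without BFP-positive replicate 2. Plac8 rose 2.67-fold from 1121 ± 145 to 2993 ± 406 CPM. Ccr9, a gut homing receptor of pDCs, fell 1.85-fold from 945 ± 41.9 to 509.8 ± 13.0 CPM. Cox6a2 fell 1.99-fold from 201 ± 2.72 to 101 ± 27.9 CPM. The pDC transcription factors Tcf4 and Irf8 did not pass, at log2 fold changes of -0.31, SE 0.13 and -0.23, SE 0.11. Of 12 surface genes that vary among pDCs, 2 rose and 2 fell (2 and 2 adjusted over the list alone), with camera's adjusted p = 0.829. Ly6c2 rose 2.47-fold and Cd9 2.80-fold, and Cd5 fell 2.10-fold. Cd8a, the other member that fell, at 1461 ± 47.5 and 1075 ± 45.5 CPM, lost its call without BFP-negative replicate 1, BFP-positive replicate 1 or BFP-positive replicate 2, where adjusted p = 0.0521, 0.198 and 0.108.

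Genes of the unfolded protein response and of secretion were lower in BFP-positive cells. Of 22 members, 9 fell (16 adjusted over the list alone). Their median log2 fold change was -0.50, with camera's adjusted p = 3.65e-06, against adjusted p = 0.311 with an estimated correlation. Hspa5, the main chaperone of the endoplasmic reticulum, went from 1591 ± 137 to 967 ± 116 CPM and Pdia4 from 682 ± 8.71 to 390.5 ± 3.51 CPM. Manf went from 812 ± 80.5 to 466 ± 49.2 CPM, and Dnajc3 fell 1.82-fold. The stress-induced Ddit3 was at 21.6 ± 0.277 and 18.3 ± 3.33 CPM and did not pass. Beside this fall, 3 of 9 B cell markers fell (4 adjusted over the list alone). As a group their median log2 fold change was -1.13, with camera's adjusted p = 0.00107, against adjusted p = 0.311 with an estimated correlation. Cd79a fell from 14.4 ± 1.09 to 1.98 ± 0.356 CPM and Fcmr from 8.96 ± 0.738 to 1.26 ± 0.156 CPM. Cd79b, the partner of Cd79a in the B cell receptor, was at 93.1 ± 4.34 and 93.5 ± 4.61 CPM and did not pass. Ribosomal protein genes were slightly lower as a group, with a median of -0.29 over 22 members and camera's adjusted p = 0.00147, against adjusted p = 0.591 with an estimated correlation. The 1 member that fell was Rpl18, with a log2 fold change of -0.49, SE 0.14 and an adjusted p of 0.0433. That call was lost when any 1 library was left out, with adjusted p = 0.0666, 0.0921, 0.05002 and 0.342 without BFP-negative replicates 1 and 2 and BFP-positive replicates 1 and 2. Adjusted over the list alone the edgeR test called 0 members; 10 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 3 each over all genes.

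Cell cycle genes were higher in BFP-positive cells, with 12 of 25 members up (14 higher and 1 lower adjusted over the list alone). The list had a median of 0.99 and camera's adjusted p = 0.000144, against adjusted p = 0.311 with an estimated correlation. The members that rose act mainly in mitosis. Ube2c rose from 18.4 ± 3.36 to 73.7 ± 2.58 CPM and Ccna2 from 22.6 ± 0.525 to 72.0 ± 3.88 CPM. Plk1 rose from 7.26 ± 2.9996 to 37.2 ± 4.55 CPM and Birc5 from 20.4 ± 2.02 to 67.2 ± 10.9 CPM. Among genes of DNA synthesis Rrm2 rose 2.29-fold, while others named here did not pass. Mcm6 was at 343 ± 2.55 and 273 ± 14.5 CPM, Pcna at 73.8 ± 4.54 and 79.4 ± 1.93 CPM and Tyms at 86.8 ± 4.86 and 93.0 ± 5.30 CPM. Immediate early and stress genes rose in 6 of 19 cases (6 higher and 1 lower adjusted over the list alone). Over the list the median log2 fold change was 0.31, with camera's adjusted p = 0.00757, against adjusted p = 0.311 with an estimated correlation. Klf6 rose 3.59-fold, Zfp36, which encodes a protein that destabilises cytokine mRNAs, 3.94-fold and Jun 3.06-fold. Egr1 stood at 3.35 ± 0.607 and 3.29 ± 0.691 CPM and the heat shock gene Hspa1a at 0.796 ± 0.0105 and 1.82 ± 0.707 CPM, neither past the test. Apoptosis and survival genes rose in 6 of 22 cases and fell in 2 (7 and 3 adjusted over the list alone), with camera's adjusted p = 0.137. Here the number that rose was 2 without BFP-negative replicate 2 and 3 without BFP-positive replicate 2. Birc2 rose 2.11-fold, the pro-apoptotic Pmaip1 3.27-fold, and Casp8 fell 1.74-fold. The other member that fell, Bcl2l1, was at 67.0 ± 4.15 and 38.5 ± 0.481 CPM. Its call was lost without BFP-negative replicate 1, BFP-positive replicate 1 or BFP-positive replicate 2 (adjusted p = 0.0682, 0.0662 and 0.0837).

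The remaining lists were not called by camera. Of 22 genes of endosomal Toll-like receptor signalling, 4 rose and 1 fell (4 and 2 adjusted over the list alone, adjusted p = 0.618). Of these, 2 rose without BFP-positive replicate 2 and 2 fell without BFP-negative replicate 2. The adaptor gene Myd88 rose 2.06-fold and Hsp90b1, the chaperone of these receptors, fell 1.70-fold. The median was 0.03 both as fitted and with Irak3, which had no count in BFP-negative and 36 in BFP-positive cells, at its bound of at least 12.7-fold higher. MHC class I genes rose in 3 of 19 cases (5 higher and 2 lower adjusted over the list alone, adjusted p = 0.953). B2m, at 7525 ± 484 and 10034 ± 778 CPM, lost its call without BFP-positive replicate 1 (adjusted p = 0.217). H2-D1, at 3071 ± 490.4 and 4185 ± 77.4 CPM, lost it without BFP-negative replicate 1 and BFP-positive replicates 1 and 2 (adjusted p = 0.107, 0.139 and 0.103). The number that rose was 1, 0 and 1 in these 3 fits, and 2 members fell in the first. Of 18 glycolysis genes, 3 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.983). The regulator Pfkfb3 rose 2.54-fold and the glucose transporter gene Slc2a3 2.61-fold, while Tpi1 fell 2.16-fold. There were 4 members that fell without BFP-negative replicate 1. Among 24 genes of oxidative phosphorylation edgeR called 0, 0 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 0 each (camera's adjusted p = 0.829, 0 adjusted over the list alone). Cox5b was at 159 ± 3.34 and 189.7 ± 12.5 CPM and Uqcrq at 592 ± 6.63 and 509 ± 13.7 CPM. In cholesterol synthesis 1 of 20 genes rose, Pmvk, 1.71-fold (1 higher and 2 lower adjusted over the list alone, adjusted p = 0.210). Insig1 was at 116 ± 3.14 and 78.3 ± 9.20 CPM (adjusted p = 0.0501), and passed with DESeq2 and limma-voom (adjusted p = 0.0273 and 0.0394).

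Among lists of other cell types, T, NK and innate lymphoid cell genes rose in 1 and fell in 2 of 9 cases (2 and 3 adjusted over the list alone, camera's adjusted p = 0.953). Klrd1, a lectin-like receptor of NK cells, rose 5.50-fold from 18.3 ± 0.0395 to 100.5 ± 11.7 CPM and Cd28 fell 2.64-fold. Granulocyte and mast cell genes fell in 1 of 8 cases (1 adjusted over the list alone, adjusted p = 0.824). This was Prg2, at 41.5 ± 54.0 and 2.92 ± 1.46 CPM, whose log2 fold change of -3.82 became -0.15 without BFP-negative replicate 2 (adjusted p = 0.948), -4.76 without BFP-negative replicate 1 and -4.45 without BFP-positive replicate 2. Csf3r was at 0.869 ± 1.00 and 5.48 ± 1.44 CPM (adjusted p = 0.0980; 0.00537 without BFP-negative replicate 2). Of 6 erythroid and progenitor genes 1 fell (1 higher and 1 lower adjusted over the list alone, adjusted p = 0.983). Pf4 had 32 counts over the BFP-negative libraries and 0 over the BFP-positive ones, at least 10.1-fold lower when set against a floor of 3 counts over the group. Its call was lost without BFP-negative replicate 2, BFP-positive replicate 1 or BFP-positive replicate 2 (adjusted p = 0.121, 0.249 and 0.267), and without BFP-negative replicate 1 it was not tested. Cd34 did not pass (log2 fold change 3.48, SE 1.16, adjusted p = 0.0858; 0.00346 without BFP-negative replicate 2). The median of the erythroid list, 0.38, was the same with Pf4 at its bound. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2, signs of RNA quality, stood at 303 ± 69.9 and 285 ± 71.9 CPM and at 3219 ± 785 and 3022 ± 818 CPM, neither past the test. Both were higher in replicate 1 than in replicate 2 of either group. In BFP-negative and BFP-positive cells, mt-Rnr2 was at 3771 and 3598 CPM in replicate 1 and at 2661 and 2442 CPM in replicate 2. Of the sex-linked genes 4 were tested and edgeR called 0, with 0 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. Uty was at 8.09 ± 0.951 and 9.84 ± 0.885 CPM and Kdm5d at 6.69 ± 0.877 and 5.25 ± 0.261 CPM.

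**Figure D3:**
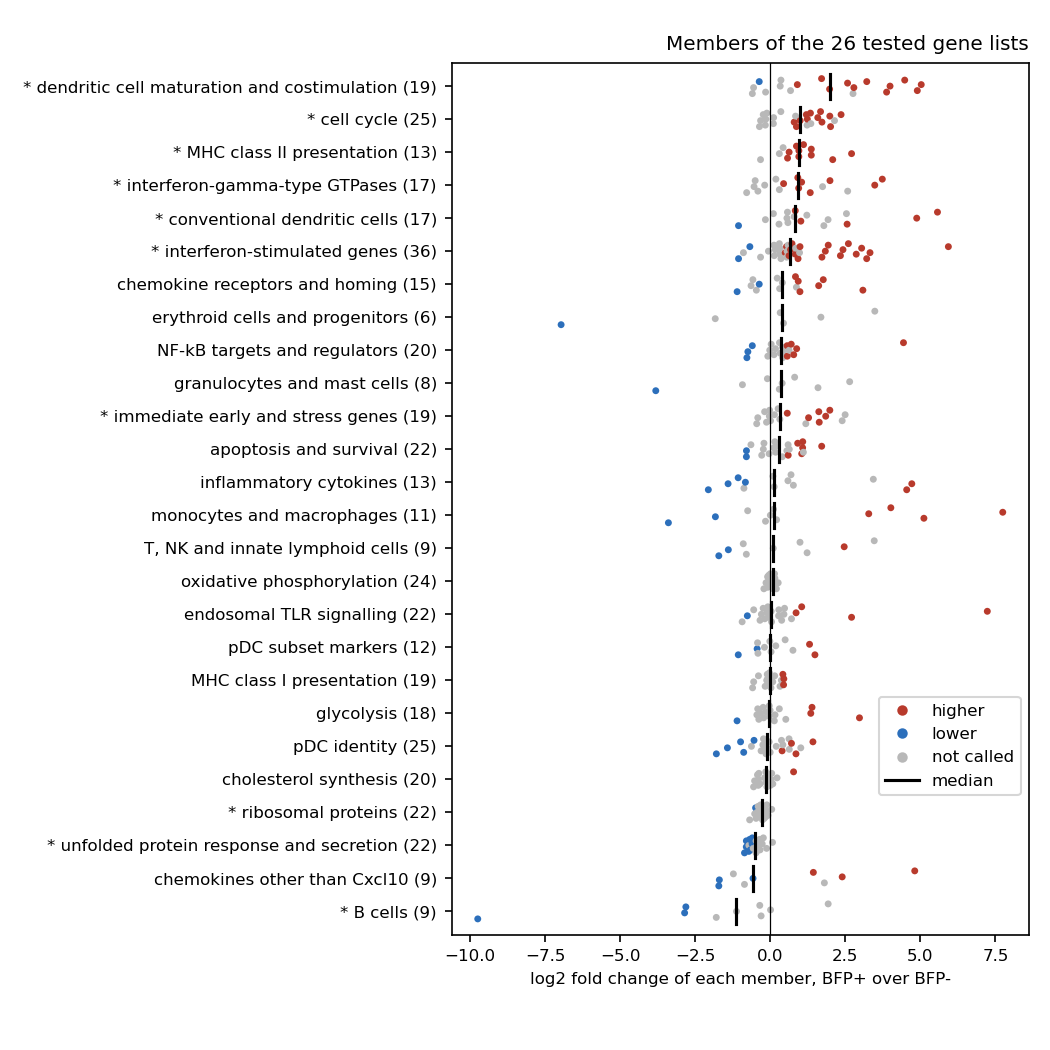
Log2 fold change of BFP-positive over BFP-negative pDCs (horizontal axis) for each tested member of the 26 gene lists (rows, with the number of tested members), red for members that were higher, blue for lower and grey for those not past the test; black bars are list medians and stars mark the 10 lists that camera called with its preset correlation. The medians run from 1.97 for dendritic cell maturation and costimulation to -1.13 for B cells, and points of genes with no count in a group, such as Pf4, show a fitted value that is no measured size.

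Camera with a preset inter-gene correlation of 0.01 called 7 lists higher and 3 lower of 26. The same test with the correlation estimated from these 4 libraries called 0, with 2 at an unadjusted p under 0.05. On simulated data with the MHC class II list shifted 1.5-fold, the preset form found that list in 5 of 5 data sets and the estimated form in 0 of 5. Fry found it in 1 of 5, and the preset form also called 1 list that had not been shifted. Genes were drawn independently in these data sets, without the correlation that separates the preset form from the estimated one. The simulation therefore cannot show whether the preset value suits lists whose genes vary together. The p-values of single genes and of fry measure the spread between these samples, which the labels do not say came from separate animals or cultures. Camera with the preset correlation compares genes with other genes under an assumed correlation. The family and phase tests of the closing section are likewise computed over genes. Their p-values are therefore no measure of replication between samples. The sign of the median, mean or test differed for several lists that were not called. Fry, a rotation test of whether a list's genes move in a common direction, pointed upward for pDC identity and glycolysis, where camera and the median pointed downward. The medians of the T, NK and innate lymphoid and the erythroid lists were above 0 where camera and fry pointed downward.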

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

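All the alternatives here were listed before the data were examined. Under 3 other scalings, 2 other filters, DESeq2, limma-voom, robust dispersion and limma on the deposited log2 RPKM values, both counts of calls stayed within 1.5 times 890 higher and 411 lower. Library totals alone gave 813 higher and 574 lower, a share of 58.6% higher against 68.4%, with the median of all genes at -0.09 against -0.02 on the log2 scale; limma on log2 RPKM gave 647 and 406, with 950 of the 1301 genes kept. Leaving out 1 library gave 559 to 921 genes higher and 245 to 408 lower, with fewer samples in each fit; the lone library of a group was then assumed to vary like the other group. The test against a fold of 1.5 called 392 higher and 68 lower, since it asks for more than a difference from 0. The Cxcl10 log2 fold change passed in every setting, with adjusted p = 0.0122 against a fold of 1.5, and ran from 3.08 to 5.68 when a library was left out.

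The 10 lists stayed called under the scalings, filters, log2 RPKM values, prior count and leave-outs tried. NF-kB targets and regulators were called as well with no filter, the stricter filter, a prior count of 0.5 and without BFP-negative replicate 2, the last together with chemokine receptors and homing. Camera with an estimated correlation called 0 lists, 2 at an unadjusted p under 0.05. Fry called 10, 7 of them shared; it left out conventional dendritic cells, ribosomal proteins and immediate early genes and added oxidative phosphorylation, monocytes and macrophages, and the erythroid list. The cause of these differences was not tested. For the single genes named by rule, 278 values from leave-outs stayed on their side of the threshold, 16 fell out of the test and 5 came into it; in the other settings the numbers were 851, 19 and 29. Among the genes named in the text, calls were lost by Ifitm1 under robust dispersion, by Prg2 with DESeq2, limma-voom, log2 RPKM and robust dispersion, by Siglech with library totals, upper-quartile factors and log2 RPKM, by H2-D1 with library totals, log2 RPKM and robust dispersion, by B2m with log2 RPKM, by Rpl18 with median-of-ratios factors and by Pf4 with no filter and DESeq2. Calls were gained by Insig1 with library totals, upper-quartile factors, the stricter filter, DESeq2, limma-voom and robust dispersion, by Rpl4 with these and no filter, by Itgam with no filter, DESeq2 and limma-voom and by Cd34 with DESeq2. For lists they were 102, 0 and 2 from leave-outs and 259, 20 and 7 otherwise, and no value reversed. Of 173 called genes from the lists and the rule, 57 lost the call without some library and 20 moved over 1.5-fold.

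The replicate numbers were tried as a pairing, and the titles give the libraries of each number a shared code, but the labels do not say whether it marks an animal, a culture or a day, and with 2 pairs the deviations of same-numbered libraries correlated at 0.0594. With the replicate block, edgeR called 1140 higher and 760 lower, limma-voom 1193 and 826, and DESeq2 904 and 448; camera called 11 lists. Fry with the replicate block called 3, interferon-stimulated genes, conventional dendritic cells and maturation; of the others that camera called, adjusted p = 0.0793 for MHC class II and for the unfolded protein response, 0.0781 for cell cycle, 0.0760 for ribosomal proteins, 0.0933 for B cells, 0.0954 for interferon-gamma-type GTPases and 0.237 for immediate early genes. The cause was not tested. Depth limits the low genes: a gene needed about 10 counts in a library to be tested, and 18 of the 19 interferon genes lay under this. For the interferon genes, lost reads of near-identical copies cannot be told apart from a low level.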

Other observations

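The gene families in the first paragraphs, and the tests of monocytes, conventional dendritic cells, plasma cells and B cells, were chosen only after the results were seen; the tests of gene length and GC content and of the cell cycle phases were set before their results. Several families of surface and calcium-binding genes had members that were higher in BFP-positive cells. Of 9 families tried, the Ifitm genes rose in 5 of 5 cases (Fisher's exact test against all other tested genes, adjusted p = 7.54e-06; Ifitm1 was not called under robust dispersion, at adjusted p = 0.0581), with Ifitm3 going from 333 ± 20.3 to 1889 ± 235 CPM and Ifitm2 from 73.0 ± 7.70 to 737 ± 129 CPM. The Ms4a family rose in 6 of 9 cases (adjusted p = 1.68e-05), with Ms4a4c at 265 ± 28.3 and 957 ± 16.3 CPM, and the Cd300 receptors in 6 of 7 (adjusted p = 5.60e-06), with Cd300a at 309 ± 41.6 and 1013 ± 67.3 CPM and Cd300e at 6.00 ± 1.89 and 101 ± 32.4 CPM. C-type lectin genes rose in 8 of 15 cases and fell in 1 (adjusted p = 7.57e-06); Clec4a3 went from 7.84 ± 0.741 to 154 ± 4.07 CPM and Clec2i from 61.9 ± 3.40 to 28.9 ± 0.631 CPM. S100 genes rose in 5 of 8 cases (adjusted p = 0.000130), with S100a6 at 256 ± 2.46 and 777 ± 50.7 CPM, and annexins in 5 of 9 (adjusted p = 0.000244), with Anxa5 at 137 ± 2.77 and 275 ± 43.2 CPM. Members that did not pass included S100a8, S100a9 and Ms4a7 (edgeR's adjusted p = 0.358, 0.816 and 0.751). Since these families were picked for their changes, their p-values are no independent evidence, and reads of near-identical Ifitm and Ms4a copies can be shared.

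Immunoglobulin genes were lower in BFP-positive cells in 17 of 50 cases (adjusted p = 4.13e-12; 10 without BFP-positive replicate 2). Ighg2c went from 920.1 ± 71.2 to 389 ± 46.3 CPM, Ighg2b from 860.2 ± 81.7 to 399.5 ± 39.1 CPM and Iglc3 from 1152 ± 81.0 to 597 ± 39.8 CPM. Nucleolar genes, among them those that make and process ribosomal RNA, fell in 10 of 48 cases (adjusted p = 7.57e-06), with Ncl, the nucleolin gene, at 107 ± 10.6 and 48.8 ± 8.16 CPM and Nop58 at 106 ± 6.41 and 56.8 ± 1.97 CPM. Histone genes rose in 15 of 52 cases (adjusted p = 7.57e-06), with Hist1h2ao at 41.5 ± 9.56 and 192 ± 25.4 CPM and Hist1h4d at 106 ± 7.20 and 241 ± 8.00 CPM, in a family of many near-identical copies.

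The rise of class II, maturation and conventional dendritic cell genes could come from other cells among the BFP-positive ones, although the sort named SiglecH and CD11b. Against monocytes or macrophages as the source of the class II rise stands Lyz2, among their most abundant transcripts. Lyz2 was itself called higher in BFP-positive cells, but its gain was small. It gained 26.1 CPM, 0.132% of the 19781 CPM that the 10 called class II genes gained together. Cd14 (10.1 ± 0.373 to 97.6 ± 2.47 CPM), Csf1r and Fcgr1 rose and fry called the monocyte and macrophage list upward (adjusted p = 0.0367), which goes with some such cells. Apoe and Adgre1 of that list fell, and camera did not call the list (adjusted p = 0.451). Lyz2 therefore speaks only against such cells as the whole source. Gene length and GC content do not account for the rise of class II, maturation and conventional dendritic cell genes. The median of the 49 members went from 0.97 to 0.86 (SE 0.26) once their trend was removed, with camera's p of 1.63e-12. That trend was small, with an SD of 0.0480 over all genes and 0.0338 over the members. The SE of a list median was taken here by resampling the genes of the list, so it does not measure the spread between libraries. Of the 20 markers of conventional dendritic cells 17 were tested, and Itgam is a gene of the sort. To account for the gain of all 890 genes that rose, 109410 CPM in sum, such cells would have to replace at least 10.9% of the RNA. If such cells carried none of the pDC identity genes, those genes would then fall to a median of -0.17 or lower. Cells that carry some of them would lower the median less. Siglech, a member of that list, is also a gene of the sort, so its level depends on the gate. A rise of the class II, maturation and conventional dendritic cell genes alone could come from a smaller share, which was not computed. The pDC identity median was -0.11 (SE 0.17 over resampled genes), so such cells and a change within pDCs cannot be told apart by it. A different state of pDCs that express Cxcl10, the difference the design names, stays open and was not tested.

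The fall of unfolded protein response genes could come from antibody-secreting or B cells among the BFP-negative ones, although the sort named SiglecH and CD11b. Against plasma cells as the source stands Jchain, among their most abundant transcripts, which fell by 9.05 CPM (SE 2.42), 0.201% of the 4506 CPM by which the list fell in sum; the immunoglobulin genes fell by 2599 CPM in sum (SE 271), which goes with such cells and may be an underestimate where reads of near-identical copies are lost, so a part played by plasma cells stays open and Jchain speaks only against them as the whole cause. Removing the trend on gene length and GC content moved the list's median from -0.51 to -0.63 (SE 0.07 over resampled genes). Camera's p was then 4.14e-07, for a trend with an SD of 0.0352 over the members. For the B cell genes, the fall of Cd79b was -0.313 CPM (SE 10.01 from the fitted model, 4.48 from the replicates alone) and that of Cd79a 12.4 CPM; since these lie within 2 SE of the fitted model, though not of the replicates, and the level of Cd79b, 93.1 ± 4.34 CPM, can hide a small share, B cells among the BFP-negative cells and a fall within pDCs cannot be told apart, and Ighm, the most abundant gene of that list, was at 2483 ± 76.0 and 2003 ± 14.3 CPM. A lower secretory activity of BFP-positive pDCs is a hypothesis that the design leaves open and that was not tested.

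The rise of mitotic genes may reflect a larger share of BFP-positive cells in G2 or M phase. Of phase genes outside the fixed list, 40 of G2 and M had a median log2 fold change of 0.84 and 34 of S phase one of 0.04, a difference of 0.80 (permutation test with 100000 resamples over genes, which are not independent replicates, p = 0.00013). The phase genes were measured in the same libraries in which the mitotic rise was seen, so the test is no independent evidence. It also does not show which cells carry these genes. Of the G2 and M genes edgeR called 10 higher, and of the S genes 0, with 4 at an unadjusted p under 0.05 and 1 called by DESeq2 and by limma-voom each. The rise of 15 of 52 histone genes, which are made mainly in S phase, goes the other way. No technical explanation of this pattern was tested.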
